A study of Mus musculus with 9 samples.

How the data were processed

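RNA from 9 samples of Hepa 1-6 cells was sequenced: 3 with a control guide, 3 with Usp5 knocked out and 3 with Ythdf1 knocked out. Per the labels' protocols, total RNA was treated with DNase and libraries were made from poly(A) mRNA, so that transcripts without a poly(A) tail are captured poorly. The deposited table holds 1 column of estimated counts per gene for each sample, written as whole numbers by the authors, with a gene symbol, a gene type and a gene length for each gene. fastp 0.23.2, STAR 2.7.10a, Salmon 1.9.0 and a mouse GRCm39 genome are named in the submitters' processing notes, without their roles or order. The annotation release is not given in the sources used here. Because Salmon estimates counts, the whole numbers were taken as estimates that had been rounded, and no further rounding was needed. Whether reads were assigned by strand is not given in the sources used here, so genes that overlap on opposite strands, and near-identical copies of a gene, can share reads and their values are uncertain.

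Columns were matched to samples by the sample descriptions, and each sample's group was taken from its title. The labels number the samples of each group but do not say that they came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. No 2 libraries agreed within counting noise. A reference annotation of another mouse build was used only for the GC content, chromosome and order of genes matched by identifier, and no coordinates from it are printed. Gene lengths were those of the deposited table.

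Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter on low counts, and the quasi-likelihood test (glmQLFit and glmQLFTest) in a fit over all 9 samples with group as its only term. Of 53647 genes, 13661 were tested. The comparisons were each knockout against control and the Usp5 knockout against the Ythdf1 knockout. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a second count also asked for a log2 fold change of at least 1 in size. Fold changes are on the log2 scale with their standard errors, and CPM values are means over 3 samples with their SD. The samples held between 24760877 and 42989715 counts each. Genes with 0 counts in a group are given as a bound against a floor of 3 counts over that group, and genes with 1 to 3 counts as a ratio with an exact 95% interval; both cover counting error only.

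A total of 44 gene lists, 12 of them immune, were fixed with the tests, the comparisons and the rule for named genes before the data were examined. Of the 463 immune genes in the table, 291 were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Camera asks whether a list ranks differently from other genes, so a list can be called where few of its members pass. With an estimated correlation, 2 of 18 called lists held in the Usp5 knockout (NF-kB and interferon-gamma genes), 0 of 14 in the Ythdf1 knockout and 4 of 22 between the knockouts; the lowest adjusted p in the Ythdf1 knockout was then 0.0783. Genes were named by rule: both targets; the 10 genes with the largest rise and the 10 with the largest fall in each comparison, among called genes with at least 5 CPM in the higher group and no overlap between groups; up to 2 called members per list and direction with at least 1 CPM; up to 10 immune genes per direction called in both knockouts and up to 5 with opposite directions; and a short set of antigen presentation and interferon genes given as values whether or not they passed. Genes without an established symbol were left out.

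Overlaps between both knockouts share their controls, so all 9 libraries, controls included, were simulated 40 times without a change between groups. The expected overlap of independent lists was also computed. The test was tried on simulated data with known changes. For the Usp5 comparison, 73% of 2-fold and 32% of 1.5-fold changes were recovered among 13396 genes. For the Ythdf1 comparison, 78% and 43% were recovered among 13378 genes. Unchanged genes were called as well, 12 in the Usp5 simulation and 10 in the Ythdf1 simulation. Only 100 genes were changed at each fold, and genes were drawn independently, while 19.8% and 46.5% of genes were called in the real comparisons. The adjusted threshold is looser there, so these rates do not describe the real tests. Alternatives were RLE scaling, library sizes alone, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a fit of only the groups compared, a replicate block, stricter thresholds, fry in place of camera, and leaving out each sample in turn. A correction that removed smooth trends of each library on GC content and gene length was added after the data had been seen.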

Results

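Transcript levels were measured by poly(A) RNA sequencing in 9 samples of Hepa 1-6 cells, a mouse hepatoma line that grows as an adherent epithelial culture. The samples form 3 groups of 3: cells carrying a control guide, cells in which Usp5 had been targeted with CRISPR-Cas9, and cells in which Ythdf1 had been targeted. Usp5 encodes a deubiquitinase that takes apart unanchored polyubiquitin chains, and Ythdf1 encodes a cytoplasmic protein that binds N6-methyladenosine in mRNA. The knockout cells are described as clones grown from single cells and checked by immunoblot. The design asks which genes, immune genes above all, change alike when either protein is lost. The control samples held 41903529, 39794048 and 24760877 counts, the Usp5 knockout samples 42989715, 29444638 and 25419118, and the Ythdf1 knockout samples 28377971, 27253550 and 27781687. Of the 53647 genes listed, 13661 had enough counts to be tested. The first principal component of log2 CPM (counts scaled to library size) carried 44.9% of the variance and the second 25.8%. Pearson correlations between libraries lay between 0.983 and 0.995 within groups and between 0.951 and 0.976 across groups. Mitochondrially encoded transcripts took 2.31%, 2.29% and 5.86% of the counts in the controls, 3.63%, 6.09% and 3.98% in the Usp5 knockout and 3.87%, 4.92% and 3.48% in the Ythdf1 knockout.

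The targeted transcripts were examined first. Usp5 (ENSMUSG00000038429) stood at 234, 224 and 184 CPM in the controls and at 123, 113 and 110 CPM in the Usp5 knockout, with means of 214 ± 26.5 and 115 ± 6.59 CPM (SD, n = 3). Its log2 fold change was -0.89 ± 0.11 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000316). Ythdf1 (ENSMUSG00000038848) stood at 190.2, 181 and 195 CPM in the controls and at 49.2, 45.7 and 49.9 CPM in the Ythdf1 knockout, with means of 189 ± 7.06 and 48.3 ± 2.22 CPM (SD, n = 3). Its log2 fold change was -1.97 ± 0.0736 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.21e-07). Neither knockout passed the test for the other target: Ythdf1 had a log2 fold change of 0.10 in the Usp5 knockout and Usp5 of 0.07 in the Ythdf1 knockout (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.368 and 0.637).

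**Figure D1:**
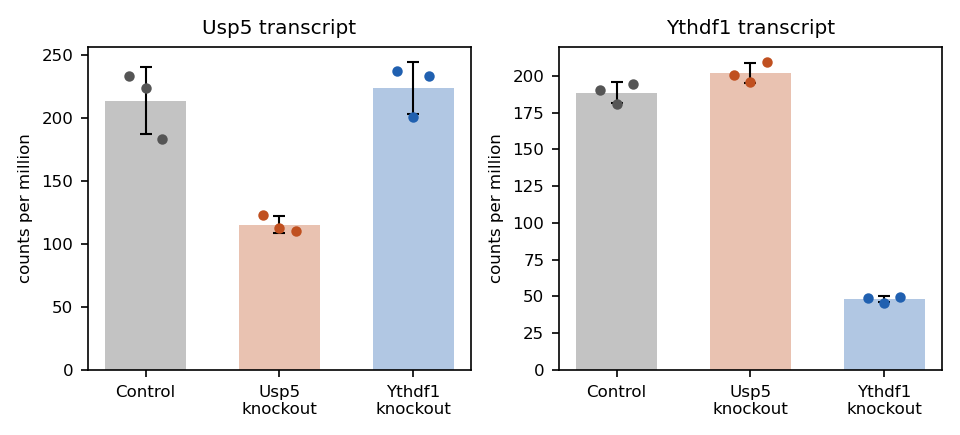
CPM of the Usp5 transcript (left) and the Ythdf1 transcript (right) in the 3 groups; points are the 3 samples of a group, bars their mean and error bars the SD. The Usp5 knockout samples lie between 110 and 123 CPM for Usp5, and the Ythdf1 knockout samples between 45.7 and 49.9 CPM for Ythdf1.

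Loss of Usp5 was compared with control to ask which transcripts depend on this deubiquitinase. NF-kB pathway and target genes were lower as a list in the Usp5 knockout, a call that held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0179). Complement C3, the central component of the complement cascade, fell from 268 ± 5.24 to 6.73 ± 0.256 CPM (SD, n = 3). The monocyte chemoattractant Ccl2 was almost lost, with 2 counts over the 3 knockout libraries against 4127 in the controls, a ratio of 1780 with a 95% counting interval from 491 to 14700. Keratin 19 (Krt19) rose by 2.28 on the log2 scale to 7.34 ± 0.242 CPM and the adhesion molecule Epcam rose from 6.39 ± 0.173 to 22.1 ± 1.96 CPM (SD, n = 3). The rise of Epcam was not particular to this knockout: its fitted level was 345% of control here and 281% in the Ythdf1 knockout. For Krt19 these levels were 485% and 144%. In all, 2700 genes (19.8%) passed the test, 1361 higher and 1339 lower, and 771 of them changed at least 2-fold, 313 higher and 458 lower.

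Within the list of NF-kB pathway and target genes, 26 of 37 tested members were lower in the Usp5 knockout, 0 were higher and 11 did not pass; adjusted over the list alone, 29 were lower. The median log2 fold change was -0.735 (camera, Benjamini-Hochberg adjusted p = 3.55e-14; adjusted p = 0.0179 with an estimated correlation). Tnfaip3, which encodes the ubiquitin-editing enzyme A20 that restrains NF-kB signalling, fell by 1.12 on the log2 scale, and the adaptor Traf3 by 1.02. The matrix metalloproteinase Mmp9 had 3 counts in the knockout against 161 in the controls, a ratio of 46.2 with a 95% counting interval from 15.5 to 226. All 3 counts came from Usp5 knockout replicate 3, and the fitted log2 fold change went from -5.32 to -8.54 without that library, so its size is uncertain. Of 35 tested interferon-gamma induced genes, 18 were lower and 3 higher (22 and 4 adjusted over the list alone), with a median of -0.487 (camera, Benjamini-Hochberg adjusted p = 2.24e-05; adjusted p = 0.0288 with an estimated correlation). The guanylate-binding protein genes Gbp9 and Gbp6 had log2 fold changes of -2.44 and -2.41, as members of a gene family whose reads can be shared between copies, while the transcription factor gene Irf8 rose by 0.56.

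Of 16 tested chemokines, 10 were lower and 2 higher (10 and 3 adjusted over the list alone), with a median of -1.58 (camera, Benjamini-Hochberg adjusted p = 0.000342; adjusted p = 0.146 with an estimated correlation). Ccl20, which attracts CCR6-bearing lymphocytes, fell by 3.25 on the log2 scale and the neutrophil attractant Cxcl5 by 3.00, whereas Cxcl15 rose by 3.07, from 7.69 ± 2.18 to 63.9 ± 9.31 CPM (SD, n = 3). Of 24 tested cytokines, 10 were lower and 4 higher, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0203; adjusted p = 0.384 with an estimated correlation). Without control replicate 3 the adjusted p was 0.0901, at a median of -0.237 against -0.213. The median was -0.0829 without control replicate 1, -0.493 without Usp5 knockout replicate 1 and -0.0217 without Usp5 knockout replicate 3, with the call kept. Lymphotoxin beta (Ltb) fell by 4.81 and the TNF family ligand Tnfsf15 by 3.76, while the alarmin Il33 rose by 1.19. Among 35 tested cytokine and chemokine receptors, 13 were lower and 4 higher (13 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0251; adjusted p = 0.138 with an estimated correlation). Il2rb, the beta chain of the interleukin-2 and interleukin-15 receptors, fell by 1.81.

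Of 14 tested acute phase genes, 6 were lower and 1 was higher (6 and 2 adjusted over the list alone), with a median of -0.259 (camera, Benjamini-Hochberg adjusted p = 0.0426; adjusted p = 0.429 with an estimated correlation). That call ended without control replicate 3 (median -0.378, adjusted p = 0.328), without Usp5 knockout replicate 1 (-0.318, 0.05) and without Ythdf1 knockout replicate 3 (-0.265, 0.0522), though the median was no smaller in size. Ceruloplasmin (Cp), a copper-carrying plasma protein, fell by 2.10 and the lipopolysaccharide-binding protein gene Lbp rose by 0.80. Type I interferon response genes (1 higher and 6 lower of 39, same counts adjusted over the list alone; adjusted p = 0.588), class I antigen presentation genes (4 and 6 of 27, likewise; 0.47), complement genes (5 and 4 of 20, likewise; 0.974) and checkpoint ligands (3 and 9 of 26, 4 and 11 adjusted over the list alone; 0.122) did not pass as lists in camera with Benjamini-Hochberg adjustment. Cd274, which encodes PD-L1, had a log2 fold change of 0.06 and B2m of 0.25 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.746 and 0.45). B2m passed without control replicate 3, at 0.59 (0.00455).

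In the Usp5 knockout, of 33 tested hepatocyte proteins and transcription factors, 13 were higher and 6 lower (17 and 7 adjusted over the list alone), with a median of 0.479 (camera, Benjamini-Hochberg adjusted p = 0.00987; adjusted p = 0.138 with an estimated correlation). Fetuin-B (Fetub) rose by 1.69 and apolipoprotein A-V (Apoa5) by 1.35, whereas tyrosine aminotransferase (Tat) fell by 4.94 and the pioneer factor gene Foxa1 by 2.03. Fitted levels in the Ythdf1 knockout were 160% of control for Fetub, 248% for Apoa5, 78.9% for Tat and 79.2% for Foxa1. Of 25 tested cholesterol biosynthesis genes and SREBP2 targets, 8 were higher and 1 lower (12 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.000331; adjusted p = 0.146 with an estimated correlation). The pathway enzymes Mvd and Dhcr7 each rose by 0.67. NRF2 targets and glutathione genes were lower in 13 and higher in 1 of 39 tested members (15 and 3 adjusted over the list alone), with a median of -0.276 (camera, Benjamini-Hochberg adjusted p = 0.000821; adjusted p = 0.138 with an estimated correlation). The quinone reductase Nqo1 fell by 2.08 and the glutathione transferase Gsta3 by 4.36. Among 24 tested fatty acid oxidation and PPARA targets, 5 were lower and 1 was higher (6 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0213; adjusted p = 0.256 with an estimated correlation), and the pantetheinase Vnn1 fell by 3.19.

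Of 45 tested extracellular matrix and mesenchymal genes, 19 were higher and 8 lower (22 and 9 adjusted over the list alone). Their median log2 fold change was 0.304 and their mean -0.0323, so the signs differ (camera, upward, Benjamini-Hochberg adjusted p = 0.000611; adjusted p = 0.112 with an estimated correlation). Thrombospondin 1 (Thbs1) rose by 1.32 and vimentin (Vim) by 1.06. Nidogen 2 (Nid2), a basement membrane protein, had 0 counts in the knockout against 124 in the controls, at least 35.6-fold lower with a floor of 3 counts over the group. Nid2 was also low in the Ythdf1 knockout, with 4 counts and a fitted level of 5.04% of control. Of 25 tested TGF-beta and SMAD targets, 6 were higher and 3 lower (10 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00866; adjusted p = 0.247 with an estimated correlation), with follistatin (Fst) up by 1.66 and Tgfbi by 1.91. The median was 0.14, and 0.229 without Usp5 knockout replicate 1. Fst and Tgfbi had fitted levels of 161.5% and 441.4% of control in the Ythdf1 knockout as well. Of 32 tested MAPK and immediate early feedback genes, 11 were higher and 2 lower (15 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00191; adjusted p = 0.153 with an estimated correlation), among them the EGF receptor ligands Areg (0.99) and Btc (0.89).

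Markers of bile duct cells, a list that also holds genes expressed by hepatoma cells, were higher in 6 and lower in 0 of 10 tested members, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00191; adjusted p = 0.112 with an estimated correlation); Krt19 and Epcam belong to it. Leukocyte markers (0 of 5 tested passing), endothelial markers (1 lower of 7) and stellate cell markers (2 higher and 2 lower of 8) were not called. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were lower in 3 and higher in 0 of 11 tested members, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00191; adjusted p = 0.157 with an estimated correlation). That list had been set as a check on RNA quality. H1f2 fell by 1.58, as 1 of a family of near-identical genes. Calls for proteasome subunits (median -0.145; camera, Benjamini-Hochberg adjusted p = 0.0273; adjusted p = 0.389 with an estimated correlation), S phase genes (0.0911; 0.0426; adjusted p = 0.256 with an estimated correlation) and Wnt targets (0.18; 0.0426; adjusted p = 0.315 with an estimated correlation) were also made. Leaving out 1 library ended them for 4, 4 and 8 of the 9 libraries, with adjusted p up to 0.06, 0.136 and 0.102. In those fits the medians lay between -0.134 and -0.149, 0.0863 and 0.126, and 0.0605 and 0.182. For Wnt targets the median was 0.116 and 0.0605 without control replicates 1 and 2 and 0.107 without Usp5 knockout replicate 2. After the GC and length correction it was 0.137, and the call was not made (0.12).

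Outside the lists, the largest changes included the proteolipid gene Mal (3.06), the neuronal cadherin Cdh10 (3.44) and the tight junction gene Cldn2 (2.21) among genes that rose. Among those that fell were the membrane serine protease hepsin (Hpn, -6.38), the myelin protein Pmp22 (-5.17) and the calcium-binding protein S100a16 (-4.69). Fitted levels in the Ythdf1 knockout were 33.9% of control for Hpn, 19.1% for Pmp22 and 140% for S100a16. The zinc finger gene Repin1 had 0 counts in the knockout against 978 in the controls, at least 280-fold lower with the floor of 3 counts over the group. The count of 2700 genes depended on single libraries: it was 1736, 1494 and 4371 without control replicates 1, 2 and 3 and 1626 without Usp5 knockout replicate 2, and 1756 when only the 6 samples of both groups were fitted. With library sizes alone as the scaling, which moved the median of all genes by -0.0843, 1026 genes were higher and 1833 lower (35.9% higher against 50.4%).

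Loss of Ythdf1 was compared with control to ask which transcripts change without this reader of methylated mRNA. Of 38 tested targets of the transcription factor ATF4, 36 were higher. The list was called with the preset correlation but not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 1.25e-18 and 0.0827). The stress-induced chromatin protein gene Nupr1 went from 5.60 ± 1.03 to 79.6 ± 7.62 CPM, the glutathione-degrading enzyme Chac1 from 5.96 ± 0.371 to 58.7 ± 4.91 CPM and the stress cytokine Gdf15 from 39.1 ± 5.61 to 261 ± 22.5 CPM (SD, n = 3). The cholesterol synthesis enzyme isopentenyl diphosphate isomerase (Idi1) went from 55.2 ± 2.69 to 13.9 ± 1.05 CPM (SD, n = 3). In all, 6350 genes (46.5%) passed the test, 3231 higher and 3119 lower, of which 1250 changed at least 2-fold, 602 higher and 648 lower. After the GC and length correction 5770 genes passed, and only 4215 of them were among the 6350.

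Of 38 tested ATF4 and amino acid response targets, 36 were higher, 0 were lower and 2 did not pass (37 higher adjusted over the list alone), with a median log2 fold change of 1.14 (camera, Benjamini-Hochberg adjusted p = 1.25e-18; adjusted p = 0.0827 with an estimated correlation). The pseudokinase Trib3, a target of ATF4 and CHOP, rose by 3.03, and the mitochondrial folate enzyme Aldh1l2 by 2.99. The glycine transporter Slc6a9, outside the list, rose by 3.36. Of 23 tested endoplasmic reticulum chaperones and unfolded protein response genes, 15 were higher and 2 lower, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00774; adjusted p = 0.103 with an estimated correlation). Ppp1r15a, the phosphatase subunit that reverses eIF2-alpha phosphorylation, rose by 2.25 and Herpud1, a component of endoplasmic reticulum-associated degradation, by 1.62. Of 30 tested p53 targets, 18 were higher and 4 lower, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000843, and 0.0827 with an estimated correlation). Gadd45a rose by 2.02 and Sesn2, which restrains mTORC1, by 1.80. Sesn2 is also a member of the ATF4 list, so these lists overlap. Of 46 tested autophagy and lysosome genes, 30 were higher and 4 lower (32 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.26e-05; adjusted p = 0.103 with an estimated correlation), among them the cargo receptor Sqstm1 (1.36) and Map1lc3a (1.26, and 0.73 after the GC and length correction).

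Of 25 tested cholesterol biosynthesis genes and SREBP2 targets, 18 were lower and 0 higher (19 lower adjusted over the list alone), with a median of -0.692 (camera, Benjamini-Hochberg adjusted p = 3.16e-08; adjusted p = 0.0827 with an estimated correlation). Idi1 fell by 1.99 and the sterol carrier Stard4 by 1.81. Of 33 tested hepatocyte proteins and transcription factors, 21 were higher and 0 lower, with the same counts adjusted over the list alone and a median of 0.67 (camera, Benjamini-Hochberg adjusted p = 3.12e-06; adjusted p = 0.0783 with an estimated correlation). The urea cycle enzyme Ass1 rose by 1.95, and transthyretin (Ttr), a thyroxine carrier, rose by 4.04 from a low level of 0.0642 CPM. Of 14 tested acute phase genes, 10 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 1.09 (camera, Benjamini-Hochberg adjusted p = 0.00178; adjusted p = 0.337 with an estimated correlation). Serpina1a and Serpina1b, copies of the alpha-1-antitrypsin gene that share reads, had log2 fold changes of 5.98 and 4.06 at levels of 2.56 and 3.33 CPM in the knockout. With a control mean of only 0.0537 CPM, the value for Serpina1a ranged from 5.28 to 9.41 when single libraries were left out, and its size is uncertain. Angptl8, a hepatic regulator of lipoprotein lipase outside these lists, rose by 3.76.

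Of 38 tested mitosis genes, 25 were lower and 1 was higher, with the same counts adjusted over the list alone and a median of -0.458 (camera, Benjamini-Hochberg adjusted p = 2.28e-05; adjusted p = 0.24 with an estimated correlation). The spindle checkpoint kinase Bub1 had a log2 fold change of -1.23 and the kinetochore protein Cenpf of -1.13, and -0.73 and -0.67 after the GC and length correction. Cytosolic ribosomal proteins were higher in 36 and lower in 1 of 75 tested members (37 and 1 adjusted over the list alone), with a median of 0.441 (camera, Benjamini-Hochberg adjusted p = 1.28e-05; adjusted p = 0.662 with an estimated correlation); Rpl35 rose by 1.03, and by 0.49 after that correction. Nuclear-encoded oxidative phosphorylation subunits were higher in 15 and lower in 1 of 44, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0121; adjusted p = 0.738 with an estimated correlation, 0.203 without control replicate 3, where the median went from 0.282 to 0.136, and 0.061 with fry). Replication-dependent histone genes were higher in 10 and lower in 0 of 11 (11 higher adjusted over the list alone), with a median of 1.8 (camera, Benjamini-Hochberg adjusted p = 0.00025, and 0.139 with an estimated correlation). Among them was H2bc8 (2.02), whose reads near-identical copies can share. This list, set as a check on RNA quality, held between 0.00119% and 0.0107% of the counts of a library. Across genes, which are not independent replicates, the fold change in this comparison correlated with GC content (r = 0.436) and with log gene length (r = -0.346). After smooth trends on GC content and length were removed from each library, the medians were -0.2 for mitosis genes, 0.0987 for ribosomal proteins, 0.0227 for oxidative phosphorylation subunits and 1.31 for histone genes, and the ribosomal protein and oxidative phosphorylation calls ended (camera, Benjamini-Hochberg adjusted p = 0.166 and 0.481).

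Of 32 tested MAPK and immediate early feedback genes, 17 were higher and 4 lower (18 and 4 adjusted over the list alone), with a median of 0.516, and 0.296 after the GC and length correction (camera, Benjamini-Hochberg adjusted p = 0.000509; adjusted p = 0.139 with an estimated correlation); amphiregulin (Areg) rose by 2.14 and the transcription factor gene Egr1 by 1.27. Class II antigen presentation genes were higher in 7 and lower in 0 of 8 (7 and 1 adjusted over the list alone), with a median of 0.595 (camera, Benjamini-Hochberg adjusted p = 0.0215; adjusted p = 0.378 with an estimated correlation). That call ended without any of 7 of the 9 libraries (medians from 0.412 to 0.576, adjusted p up to 0.103) and after the GC and length correction (0.402, 0.135). TGF-beta and SMAD targets were higher in 11 and lower in 4 of 25 (12 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0451; adjusted p = 0.392 with an estimated correlation), with a median of 0.191. That call ended without any of 4 libraries (medians from 0.127, without Ythdf1 knockout replicate 2, to 0.19; adjusted p up to 0.0681). After that correction it was not made either (0.0568), while the median rose to 0.28.

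Other immune lists were not called. Type I interferon response genes were higher in 4 and lower in 12 of 39, interferon-gamma induced genes in 6 and 3 of 35 (4 and 2 adjusted over the list alone), class I antigen presentation genes in 8 and 1 of 27 (6 and 1), chemokines in 9 and 3 of 16, cytokines in 11 and 4 of 24, and NF-kB genes in 12 and 12 of 37 (15 and 13). Where no second pair is given, the counts adjusted over the list alone were the same. Their camera tests gave Benjamini-Hochberg adjusted p of 0.321, 0.94, 0.231, 0.1, 0.161 and 0.936. After the GC and length correction, 5 class I genes were higher and 3 lower, with the median going from 0.201 to -0.00448, and 8 cytokines were higher and 5 lower (0.324 to 0.162). Oasl1, a 2'-5'-oligoadenylate synthetase-like gene, fell by 2.88, and Cd274 rose by 0.72, from 15.2 ± 1.54 CPM (SD, n = 3; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000592). B2m had a log2 fold change of 0.48 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0881), which passed without control replicate 3 at 0.82 (0.000393), without a filter (0.021) and after the GC and length correction (0.0162). H2-K1 was listed with 0 counts in the controls, 1 in the Usp5 knockout and 3 in the Ythdf1 knockout, too few to test.

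The genes that fell furthest included the paired box factor Pax5 (-4.56), the cullin-associated protein Cand2 (-5.31), Pnma5 (-4.15) and the actin-binding protein Shroom4 (-4.09). The clock-associated repressor Ciart (3.83) and the stromelysin Mmp3 (2.82) were among those that rose furthest. With library sizes alone as the scaling, which moved the median of all genes by -0.143 on the log2 scale, 2159 genes were higher and 4185 lower (34% higher against 50.9%), so that directions are relative to the TMM scaling.

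**Figure D2:**
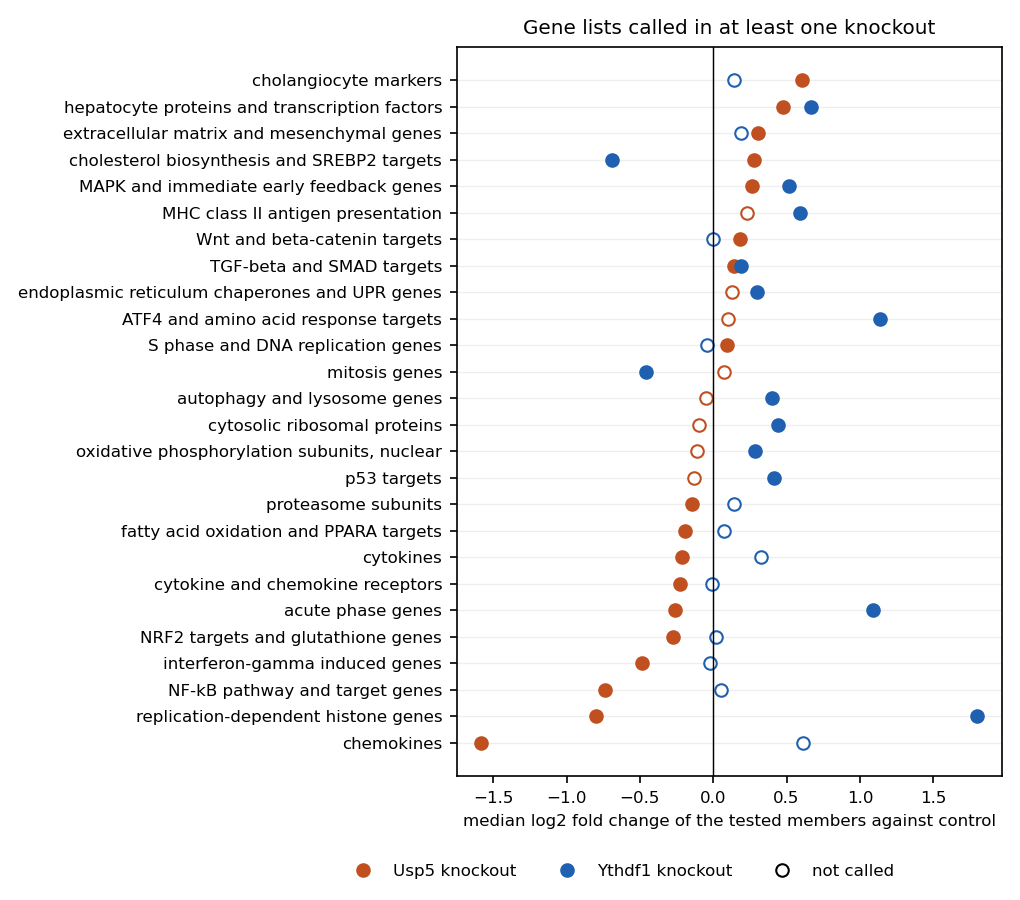
Median log2 fold change of the tested members of each gene list against control (horizontal axis) in the Usp5 knockout (orange) and the Ythdf1 knockout (blue), for lists called in at least 1 of them; filled points were called by camera with the preset correlation. ATF4 targets stand at 1.14 in the Ythdf1 knockout and 0.0987 in the Usp5 knockout, and NF-kB genes at 0.0524 and -0.735.

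The comparison that the design names sets both knockouts side by side. Among the 291 tested members of the 12 immune lists, 22 were higher in both knockouts and 33 lower in both. The lung chemokine Cxcl15 rose in both, by 3.07 in the Usp5 knockout and 2.50 in the Ythdf1 knockout. Cxcl5 fell by 3.00 and 1.13, and Nt5e, the CD73 ectoenzyme that makes adenosine, by 3.66 and 2.71. A further 30 genes changed in opposite directions, 29 of them lower without Usp5 and higher without Ythdf1, such as the neutrophil chemokine Cxcl2 (-2.71 and 2.47).

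Adjusted over the list alone, 24 immune genes were higher in both, 36 lower in both and 32 opposite. Of the 291 genes, 33 were higher and 101 lower in the Usp5 knockout, and 84 higher and 66 lower in the Ythdf1 knockout; independent lists of those sizes would share 9.53 higher, 22.9 lower and 36.6 opposite genes. Among the shared increases, the class Ib gene H2-Q1, whose reads can be shared with related genes, rose by 1.62 and 1.68, from 8.17 ± 1.42 to 25.3 ± 4.53 and 26.3 ± 2.27 CPM (SD, n = 3). Irak3, which dampens Toll-like receptor signalling, rose by 0.82 and 0.84. The lysosomal thiol reductase Ifi30, which serves class II antigen processing, rose by 0.77 in each, and by 0.41 in the Ythdf1 knockout after the GC and length correction. Lbp rose by 0.80 and 1.38, the chaperone clusterin (Clu) by 0.73 and 0.90 (0.59 in the Ythdf1 knockout after that correction), and the lectin pathway protease Masp1 by 0.97 and 0.68. The mucosal chemokine Cxcl17 went from a low level of 0.361 CPM to 2.22 CPM in the Usp5 knockout and rose by 2.04 in the Ythdf1 knockout.

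Among the shared decreases, Ccl2 fell by 2.17 in the Ythdf1 knockout beside its near loss in the Usp5 knockout. Il2rb fell by 1.81 and 1.35, Oasl1 by 1.27 and 2.88, the antiviral gene Samd9l by 0.93 and 2.02, and Ltb by 4.81 and 1.00 (-1.51 in the Ythdf1 knockout after the GC and length correction). Traf3, which restrains noncanonical NF-kB signalling, fell by 1.02 and 0.93. Raet1d, a ligand of the activating receptor NKG2D with close paralogs that share reads, had 0 counts in the Usp5 knockout against 54 in the controls, at least 15.5-fold lower. It had 1 count in the Ythdf1 knockout, a ratio of 38.1 with a 95% counting interval from 6.55 to 1530. For the 30 opposite genes, Ccl20 had log2 fold changes of -3.25 and 1.81, the growth factor gene Csf2 of -2.72 and 1.39. The invariant chain Cd74 fell by 3.31 in the Usp5 knockout and went from 0.648 to 1.81 CPM in the Ythdf1 knockout. For these, the direct test between both knockouts gave -5.19 for Cxcl2, -5.06 for Ccl20, -4.81 for Cd74 and -4.11 for Csf2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.61e-07, 1.63e-07, 2.21e-05 and 2.46e-06).

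**Figure D3:**
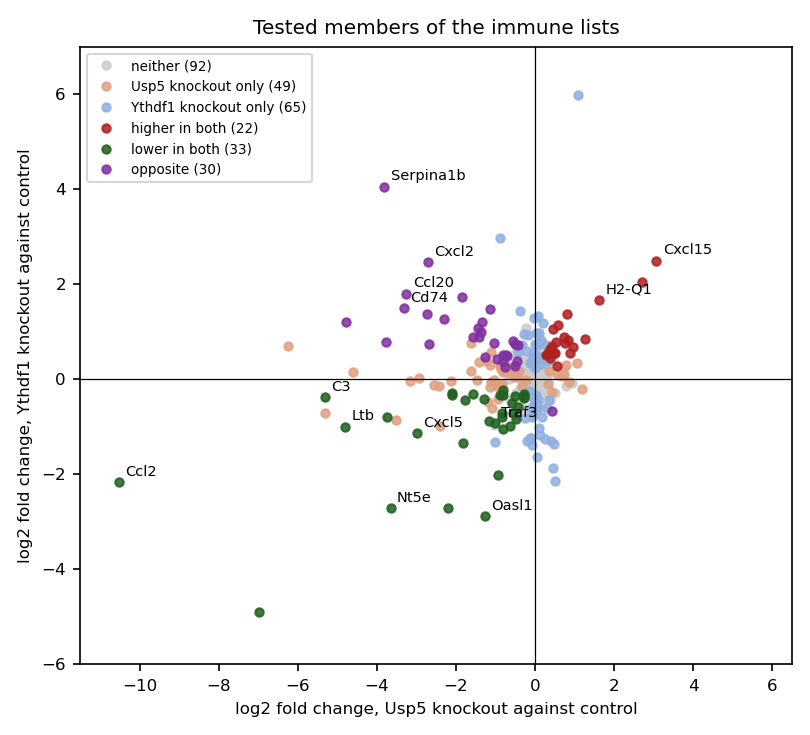
Log2 fold change against control of the 291 tested members of the immune lists in the Usp5 knockout (horizontal) and the Ythdf1 knockout (vertical); each point is a gene, coloured by the tests it passed. There are 22 genes higher in both, 33 lower in both and 30 opposite, nearly all of these in the upper left; positions of genes with 3 counts or fewer in a group, such as Ccl2, are fitted values that depend on the prior count.

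Over all 13661 tested genes, 1178 changed in the same direction in both knockouts, 608 higher and 570 lower, and 427 in opposite directions. Independent lists would share 322 higher, 306 lower and 627 opposite genes. In 40 simulations of unchanged groups with shared controls, the mean was 0.025 genes in the same direction and 0 opposite. The simulated libraries, controls included, were drawn gene by gene without library-wide trends. Counts near 0 were thus set by that design and do not show how many calls the real controls bring to both comparisons. Fold changes correlated across genes, which are not independent replicates, with r = 0.316, where the simulated shared controls gave a mean of 0.485. The covariance of the fold changes was 0.182 against a simulated 0.0266, a difference of 0.155. The 3 controls cannot be split into parts of at least 2 libraries, so part of any excess may come from the shared controls. Single genes lost in both included Xlr3c, a gene of an X-linked multicopy family, with 0 counts in either knockout against 634 in the controls, at least 182-fold and 149-fold lower. The renin-binding protein Renbp had log2 fold changes of -5.38 and -5.35 and sarcosine dehydrogenase (Sardh) of -3.08 and -5.14. The same-direction count was 598 without control replicate 2, 1874 without control replicate 3 and 719 without Usp5 knockout replicate 2. The opposite count was 235 and 219 without control replicates 1 and 2, 272 without Usp5 knockout replicate 2 and 267 and 268 without Ythdf1 knockout replicates 1 and 3. With library sizes alone as the scaling, 353 genes were higher and 933 lower in both (27.4% higher against 51.6%), and 16 and 43 immune genes (27.1% against 40%).

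Both knockouts were also compared with each other in the same fit. In this test 6627 genes (48.5%) passed, 3188 higher and 3439 lower in the Usp5 knockout, 730 and 926 of them at least 2-fold. Nupr1 had a log2 difference of -4.23, S100a16 of -5.18 and C3 of -4.94, while Cdh10 (6.24), Cand2 (4.88) and Cldn2 (3.45) were higher in the Usp5 knockout. Cd274 had a log2 difference of -0.66 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000925).

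Of 38 ATF4 targets, 36 were lower in the Usp5 knockout than in the Ythdf1 knockout and 0 higher, with the same counts adjusted over the list alone (median -1.04; camera, Benjamini-Hochberg adjusted p = 1.47e-16; adjusted p = 0.0631 with an estimated correlation). NF-kB genes were lower in 26 and higher in 2 of 37 (26 and 4 adjusted over the list alone; median -0.866; camera, Benjamini-Hochberg adjusted p = 6.33e-08; adjusted p = 0.0499 with an estimated correlation). Interferon-gamma induced genes were lower in 21 and higher in 4 of 35 (21 and 5 adjusted over the list alone; median -0.658; camera, Benjamini-Hochberg adjusted p = 0.000517; adjusted p = 0.0499 with an estimated correlation). Acute phase genes were lower in 11 and higher in 0 of 14, with the same counts adjusted over the list alone (median -1.29; camera, Benjamini-Hochberg adjusted p = 2.97e-06; adjusted p = 0.118 with an estimated correlation). Cholesterol synthesis genes were higher in 22 and lower in 0 of 25, with the same counts adjusted over the list alone (median 0.921; camera, Benjamini-Hochberg adjusted p = 3.4e-11; adjusted p = 0.0499 with an estimated correlation). Mitosis genes were higher in 29 and lower in 0 of 38, with the same counts adjusted over the list alone (median 0.517; camera, Benjamini-Hochberg adjusted p = 3.64e-07; adjusted p = 0.118 with an estimated correlation). Histone genes were lower in 11 of 11, with the same count adjusted over the list alone (median -2.73; camera, Benjamini-Hochberg adjusted p = 4.65e-06; adjusted p = 0.0631 with an estimated correlation). Across genes, this difference correlated with GC content at r = -0.314. Camera called 22 of the 44 lists in this comparison, 5 higher and 17 lower, and 4 with an estimated correlation.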

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

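The tests for a difference between cells grown as separate clones, for a few strongly changed genes and for an added copy of chromosome 16 were chosen after the result had been seen, as was the correction for GC content and length. Lists and named genes are given here when they were called in both knockouts with opposite directions and the direct test between the knockouts also passed.

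Acute phase genes (direct median log2 difference, Usp5 knockout minus Ythdf1 knockout, -1.29), cholesterol synthesis genes (0.921) and replication-dependent histone genes (-2.73) met that description as lists with the preset correlation. None of their calls against control held with an estimated correlation: camera with Benjamini-Hochberg adjustment gave 0.429 and 0.337, 0.146 and 0.0827, and 0.157 and 0.139 in the Usp5 and Ythdf1 knockouts. The acute phase call in the Usp5 knockout also ended without any of 3 libraries (up to 0.328), at medians from -0.265 to -0.378 against -0.259 with all of them. Among immune genes it held for Cxcl2 (-5.19), Ccl20 (-5.06), Cd74 (-4.81), Csf2 (-4.11) and Serpina1b (-7.87), the last at 1 count in the Usp5 knockout and as a fitted value that depends on the prior count. It also held for the adhesion genes Cdh10 (6.24) and Cldn2 (3.45), the filament gene Vim (1.81), the calcium-binding protein S100a16 (-5.18) and Shroom4 (4.77). In metabolism and stress it held for Aldh1l2 (-4.55), Dhcr7 (1.64), the lipid droplet protein Plin2 (-1.43) and Sqstm1 (-1.91), and among histones for H1f2 (-2.52) and H2bc8 (-3.35). The histone list had been set as a check on RNA quality. The rise of S100a16 in the Ythdf1 knockout, at 0.49, was no longer called after the GC and length correction, at 0.08 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.398).

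NF-kB genes had a median log2 fold change of -0.735 in the Usp5 knockout. The median was -0.735 after the GC and length correction, -0.73 without control replicate 3 and -0.632 after subtracting the level of each gene's neighbours on its chromosome. These values argue against library trends, that control library and copy changes of broad segments that hold the list's own genes as the whole cause. The subtraction cannot show the effect of a copy change elsewhere in the genome, or of one smaller than the stretch of neighbours. In the Ythdf1 knockout the median was 0.0524, which leaves open whether the cells of the Usp5 knockout differ as clones for reasons other than Usp5, since all 3 samples may descend from 1 clone. That Usp5 loss lowers NF-kB output is a hypothesis that these samples cannot separate from such a difference.

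ATF4 targets had a median of 1.14 in the Ythdf1 knockout. The median was 0.945 after the GC and length correction, 1.07 without control replicate 3 and 1.08 after subtracting neighbouring genes. These values argue against the same explanations, with the same limit on copy changes. In the Usp5 knockout the median was 0.0987, so a difference between clones, or in the medium at harvest, may account for the rise and stays open beside an effect of Ythdf1.

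Genes of chromosome 16 were shifted as a block in the Usp5 knockout: the median over 404 tested genes was 0.29, with 83.9% of them positive and 151 called higher against 8 lower, where the medians of the other chromosomes lay between -0.106 and 0.0477. The median was 0.319 after the GC and length correction and 0.32 without control replicate 3, and the lowest median of any 51 neighbouring genes was 0.209, which argues against library trends, that control and a few strong genes. A candidate explanation is an added copy of chromosome 16 in these cells: the 3 Usp5 knockout libraries stood at 0.279, 0.324 and 0.365, the lowest of them 0.226 above the highest control. The Ythdf1 knockout libraries stood at -0.187, -0.187 and -0.181. No DNA was measured.

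Other splits of the samples were refitted. For each comparison of 3 against 3 samples, 10 splits exist, too few for a share under 0.05. In each, 1 split, the real one, gave as many calls: 2700 genes against at most 1 in the other splits for the Usp5 knockout, 6350 against 0 for the Ythdf1 knockout and 6627 against 0 between the knockouts. For lists the values were 18 against at most 8, 14 against at most 11 and 22 against at most 17. Each other split mixes both groups, so a real difference between them widens its spread and few gene calls are set in advance. These splits therefore do not decide whether the gene counts exceed chance. Mixed groups still gave up to 8, 11 and 17 list calls with the preset correlation, so list calls also arise without intact groups. Of 100 divisions of the 9 samples into 3 groups, 2 gave as many genes changed alike as the real count of 1178, the real division included, and 2 gave as many as the 55 immune genes. The other such division was the real one with the Ythdf1 knockout libraries in the place of the controls (3370 and 62). The next highest counts were 104 and 6, so the counts follow whether the groups are kept whole, and this test does not decide whether the knockouts change alike beyond chance.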

How the results depend on the processing

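The GC and length correction was added after the data had been seen; all other alternatives were planned. No named gene that passed and no called list reversed its direction, and 149 of 153 named gene results kept their call at an adjusted p of 0.05 in each other fit that tested them; the stricter filter kept 127 of them for testing. Lists were retested only with an estimated correlation, fry, the block, the correction and single libraries left out, and 6 of 54 called lists kept their call in all of these. Over all genes, the correction changed many calls of the Ythdf1 comparison: 5770 genes were called with it and 6350 without it. Only 4215 genes were called both ways, 4201 of them in the same direction. With library sizes alone the median of the uncalled NF-kB list in the Ythdf1 knockout went from 0.0524 to -0.0934. Except where an alternative is stricter or uses fewer samples, the cause of a difference was not tested. Fitting only the groups compared gave 1756 genes for the Usp5 knockout and 273 opposite genes. At an adjusted p under 0.01, 1305 genes were called for the Usp5 knockout, 4363 between the knockouts, 500 alike in both and 159 opposite, and 30 and 19 among immune genes. At least 2-fold, the counts were 771, 1250 and 1656 for the comparisons, 200 alike and 69 opposite, and 3 higher and 7 lower immune genes alike. An estimated correlation left 2, 0 and 4 lists, and fry, which does not compare a list with other genes, called 32 for the Ythdf1 knockout and 39 between the knockouts. Leaving out each library in turn gave 1494 to 4371 genes for the Usp5 knockout, 598 to 1874 alike in both and 219 to 613 opposite. The replicate numbers gave no clear pairing of the samples. Same-numbered deviations correlated at 0.298, -0.116 and 0.15 between the Usp5 knockout and control. They correlated at 0.127, -0.178 and -0.257 between the Ythdf1 knockout and control, and at 0.19, 0.0882 and -0.00394 between the knockouts. Of the 9 samples, 3 correlated best with their own number. The correlation with GC content fell with the number in the controls (-0.0215, -0.265 and -0.563) and in the Usp5 knockout (0.102, -0.162 and -0.365). With 3 samples per group, a batch shared by number cannot be excluded. With the number as a replicate block, 2346, 6198 and 6458 genes, 1025 alike, 375 opposite and 48 immune genes alike were called, with 18, 13 and 21 lists and r = 0.32.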

Other observations

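The GC and length correction quoted here was added after the data had been seen; the gene lists and their tests were planned.

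In the Ythdf1 knockout the lists of this paragraph were not called. Of 22 tested fatty acid synthesis and lipogenesis genes, 5 were higher and 8 lower, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.176), and 3 and 10 after the GC and length correction (0.135). The desaturase Scd2 went from 1480 to 448 CPM and the elongase Elovl6 fell by 1.98 on the log2 scale, while the triglyceride synthesis enzyme Dgat2 rose by 1.84 and the lipid droplet protein Plin2 by 1.03. Of 32 tested glycolysis and hypoxia targets, 14 were lower and 3 higher, again with the same counts over the list alone (camera, Benjamini-Hochberg adjusted p = 0.062). After the GC and length correction, 20 were lower and 4 higher and the list was called (camera, Benjamini-Hochberg adjusted p = 0.00108). The mitophagy receptor Bnip3 fell by 2.41, and Ndrg1, which is also induced by stress, rose by 2.16. Of 17 tested cytosolic heat shock proteins, 9 were lower and 3 higher (9 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.107), with the chaperones Hsp90aa1 and Dnaja1 down by 0.95 and 0.98 and Hspb8 up by 1.00.

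Among genes that act near the targeted proteins, the list of ubiquitin genes and deubiquitinases was not called in either knockout (5 higher and 4 lower of 47 without Usp5, 12 and 15 without Ythdf1; adjusted over the list alone 8 and 8, and 12 and 16; camera, Benjamini-Hochberg adjusted p = 0.925 and 0.595). The ubiquitin gene Ubb rose by 0.90 in the Usp5 knockout, a call that ended without any of 4 of the 9 libraries at values from 0.73 to 0.85 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.0856). The proteasome-bound deubiquitinase Usp14 had a log2 fold change of -1.03 in the Ythdf1 knockout, and of -0.68 after the GC and length correction. Of 26 m6A writers, erasers and readers, 2 were higher and 1 lower without Usp5, and 3 and 12 without Ythdf1, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.942 and 0.0684). After the GC and length correction, 7 were higher and 7 lower without Ythdf1, and the median went from -0.209 to 0.0333 (adjusted p = 0.926 by the same test). The snRNA and mRNA methyltransferase Mettl16 fell by 0.60 without Usp5. Its fitted level was about the same in both knockouts, at 65.9% of control without Usp5 and 66.3% without Ythdf1. The catalytic subunit Mettl3 rose by 0.56 without Ythdf1, to 148% of control, and stood at 117% without Usp5. Of 23 tested YAP and TEAD targets, 6 were higher and 6 lower without Usp5 and 7 and 5 without Ythdf1 (6 and 8, and 8 and 5, adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.925 and 0.226). The matricellular protein Ccn2 rose in both knockouts, by 1.49 and 1.26.

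The controls did not sit together on every measure. Across genes, the correlation of each library's log2 CPM deviation with GC content was -0.0215, -0.265 and -0.563 in the controls, 0.102, -0.162 and -0.365 in the Usp5 knockout and 0.453, 0.181 and 0.469 in the Ythdf1 knockout. Without control replicate 3, 9 of the 13 mitochondrially encoded genes were called higher in the Usp5 knockout, against 1 with it (camera, Benjamini-Hochberg adjusted p = 0.00384 and 0.0939). The SD of the median fold change over 256 stretches of neighbouring genes was 0.106 in the Usp5 knockout and 0.201 in the Ythdf1 knockout, and 0.101 and 0.11 after the GC and length correction.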
